A study of Mus musculus with 4 samples.

How the data were processed

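CUT&Tag was carried out on haematopoietic stem cells sorted from the bone marrow of wild-type C57BL/6J mice as lineage-negative, Sca-1-positive, Kit-positive cells that lacked CD48 and carried CD150. In CUT&Tag, an antibody tethers a transposase to chromatin, and the tagged DNA is amplified and sequenced. Each library was made from 2000 to 5000 cells with 17 to 20 PCR cycles, per the labels' protocols. The 4 libraries fall into 2 groups by antibody. One antibody was raised against ATF2 phosphorylated at T69/71 and the other against ATF2 phosphorylated at S490/498, with 2 libraries each. The sample titles give the first site as T69/71, whereas the antibody field of the same samples gives T67/71; the titles are followed here. An IgG control and an input library are not analysed here, so no background was measured in control samples. The labels do not say whether the 2 libraries of an antibody came from separate mice, and any spread between them may be technical.

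The deposited files are peak lists, 1 per library. Per the submitters' processing notes, the tools were FastQC 0.11.5, Bowtie2 2.2.9, MACS2 and ChIPseeker, and the genome build was mm10. The MACS2 settings and its version are not given in the sources used here, nor is the removal of duplicate reads. Peak ends on chromosome 1 lie beyond that chromosome's length in the next assembly, which excludes only that assembly. The build mm10 (GRCm38) rests on the submitters' notes. Each library has its own list, and peaks were not merged between libraries. For each peak the authors deposited a fold enrichment (a ratio) at the summit over the local background. The deposited −log10 p and −log10 q values also refer to the summit. The deposited score is the −log10 q value multiplied by 10 and cut to a whole number. The smallest deposited −log10 q value lay between 1.31 and 1.39 in all 4 lists, so the lists hold peaks with q under 0.05. No list held a region more than once. Fold enrichment and q are the authors' values throughout and were used to rank and filter peaks within a list. Each fold is relative to its own library's background, so folds of different lists set side by side are descriptive.

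The lists give no read counts, so the depth was recovered from the peak values. In MACS2, fold enrichment is (pileup + 1)/(background + 1), and p is the Poisson probability of more than the observed pileup. Both equations were solved for a whole-number pileup and a background at every peak with −log10 p of at most 250. A solution within 0.001 of the deposited −log10 p was found for 100% of peaks in 3 libraries and for 99.8% in replicate 2 of S490/498. The lowest background in a list is the genome-wide one, which is proportional to reads times fragment length. Intervals on shares are exact binomial 95% intervals and cover counting error only; peaks are not independent replicates.

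Gene positions came from a RefSeq gene table of GRCm38.p6, the assembly of the files, with 21887 protein-coding genes on chromosomes 1-19, X and Y. The table gives no strand. The planned promoter definition was therefore applied to both ends of a gene: a peak counted when its summit lay within 1 kb of either end, called a gene end below. Such a count takes in the 3' end as well as the start. Genome sequence was not used here, so the planned counts of CRE and other motifs, and the background limited to CpG-rich promoters, were not made. Peaks on other sequences than these chromosomes were counted and then left out. No list of regions with high signal whatever the antibody was applied to the peaks here.

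Peaks were called shared when they overlapped by at least 1 bp. Shared regions of an antibody are the merged peaks that had a partner in the other library. Chance overlap came from 200 seeded shuffles of peak positions within their chromosomes, between the first and last annotated gene (50 shuffles where peaks were compared with either library of an antibody). The shuffles do not keep peaks near gene ends, so an excess over them does not by itself show common binding. Shares of peaks were compared between antibodies with an exact two-sided permutation test of the 4 library values. Gene lists, fixed before the data were examined, were tested with Fisher's exact test (two-sided) against all other protein-coding genes. Benjamini-Hochberg adjustment was over the 42 tests of 21 lists and 2 antibodies, or over 21 lists where a single library was tested; the alternatives kept the 42 tests. These tests compare genes within these peak lists, and genes are not replicates. One symbol of the erythroid list was not matched, and no gene stood in more than 1 list. Genes were named by a rule fixed in advance. It took Dek and Atf2, and the 10 genes per antibody with the best mean rank of −log10 q in both libraries. It also took up to 4 members per list with a peak in the most libraries, and the 5 strongest shared regions per antibody over 1 kb from a gene end. Some genes that this rule took are not reported here.

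The code was tested on simulated data. All of 500 simulated pileups were recovered. With 3000 planted shared peaks, 3045 were found, where shuffling gave 52.9. A list of 18 genes raised from a simulated share of 21% to 60% was called in 71 of 100 runs, and lists without an effect were called 0.04 times per run. These runs drew genes independently and adjusted over 21 lists. They do not cover neighbouring genes that share a peak, or adjustment over 42 tests. Alternatives covered the overlap rule, the threshold (−log10 q of at least 5), equal numbers of peaks, the distance to a gene end (3 kb) and leaving out each library. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.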

Results

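Binding of phosphorylated ATF2 was profiled in sorted mouse haematopoietic stem cells with 2 antibodies. ATF2 is a leucine-zipper transcription factor of the ATF/CREB family that pairs with Jun proteins. Its N-terminal residues T69 and T71 are known targets of stress-activated kinases, and S490 and S498 are known targets of the DNA damage kinase ATM. The series' title places the work in a study of DEK, a chromatin protein, in Fanconi anaemia, an inherited failure of DNA crosslink repair. Each antibody was used on 2 libraries of wild-type cells. On chromosomes 1-19, X and Y, T69/71 gave 12464 peaks in replicate 1 and 14716 in replicate 2. S490/498 gave 7132 peaks in replicate 1 and 435 in replicate 2. The peaks covered 4.52, 4.20, 2.45 and 0.252 Mb in the same order, with median widths of 302, 243, 290 and 411 bp.

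The peaks rested on few fragments. The recovered pileup at the summit had a median of 9 fragments in each T69/71 library, 8 in replicate 1 of S490/498 and 17 in replicate 2. The genome-wide background coverage was 0.117 and 0.105 in the T69/71 libraries, 0.0874 in replicate 1 of S490/498 and 1.52 in replicate 2. Replicate 2 of S490/498 thus had 17.4 times the background of replicate 1. Its peaks also lay more often on sequences outside the assembled chromosomes, at 8.61% (95% interval 6.25 to 11.5) against 0.190% to 0.224% in the other libraries.

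**Figure D1:**
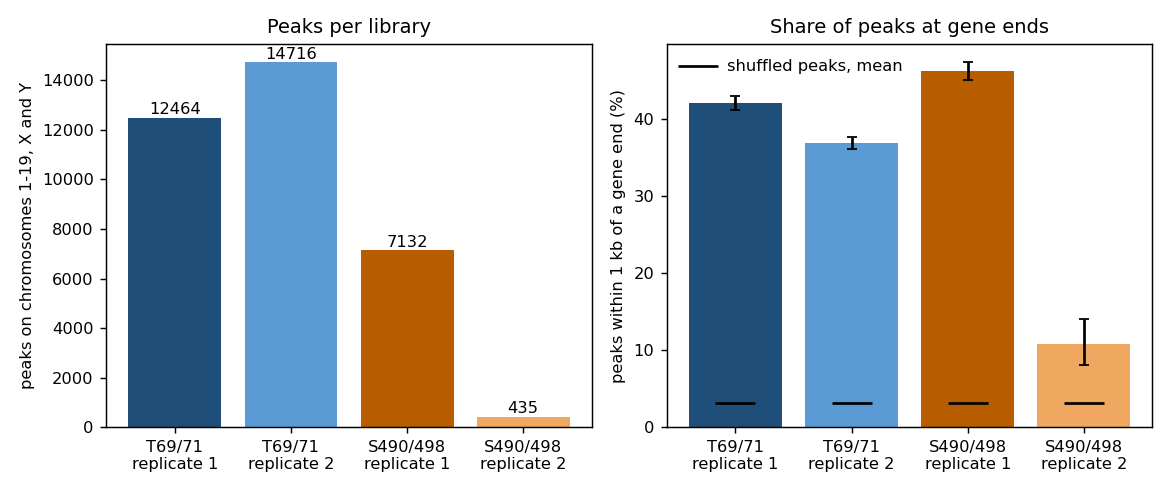
The left panel shows the number of peaks per library on chromosomes 1-19, X and Y. The right panel shows the percentage of those peaks whose summit lay within 1 kb of a protein-coding gene end, with exact 95% binomial intervals as bars and the mean of 200 shuffles as black dashes; replicate 2 of S490/498 had 435 peaks and a share of 10.8%, against 37.0% to 46.3% in the other libraries.

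The first question was whether each antibody marked the same regions in its replicate libraries. For T69/71, 7034 regions had a peak in both libraries, against a mean of 49.1 after shuffling. Every pair of libraries, within or between antibodies, exceeded shuffling, by 102 to 184 times. The excess therefore does not tell the antibodies apart. Of the peaks in replicate 1 of T69/71, 56.5% (55.6 to 57.4) had a partner in its replicate 2. The strongest shared peak at a gene end by mean rank lay at Jun, which encodes the AP-1 subunit that dimerises with ATF2. It spanned chromosome 4, 95051925 to 95052791 in replicate 1, across the upper end of the gene, with a fold enrichment of 18.2 in replicate 1 and 14.6 in replicate 2. The other leading genes were Lars2 (mitochondrial leucyl-tRNA synthetase), Cic (a transcriptional repressor), the deubiquitinases Usp36 and Usp22, Napa, Csnk1g2, Abhd11 and the neighbours Acbd7 and Rpp38, which share 1 peak. Fold enrichment was 30.9 and 42.5 at Lars2, 22.4 and 19.3 at Usp36 and 13.7 and 13.4 at Cic in replicates 1 and 2. The Lars2 site also had a peak in both S490/498 libraries. Signal that arises there with any antibody was not separated from binding.

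For S490/498, 174 regions had a peak in both libraries, against a mean of 0.96 after shuffling. They made up 40.0% (35.4 to 44.8) of the peaks in replicate 2 but 2.62% of those in replicate 1. The same replicate 2 peaks had a partner in the longer T69/71 lists at 45.1% (40.3 to 49.9) in replicate 1 and 54.5% (49.7 to 59.2) in replicate 2. Those lists held 12464 and 14716 peaks, against 7132 in replicate 1 of S490/498. Among the 435 strongest peaks of each library, the share was 16.3% (13.0 to 20.1) with replicate 1 of S490/498. With T69/71 it was 16.6% (13.2 to 20.4) and 20.0% (16.3 to 24.1), so at equal size the intervals overlapped. Of the 174 regions, 156 (89.7%) overlapped regions shared by the T69/71 libraries. This overlap does not separate common binding from signal that arises with any antibody. The genes with the strongest peaks in both S490/498 libraries were Lars2, Cic, Abhd11, Usp22, Ppm1b, Sf1, Amz2, Ensa and the neighbours Izumo4 and Mob3a. Lars2, Cic, Abhd11 and Usp22 were also among the 10 leading genes of T69/71. All 10 leading genes of S490/498 had a peak in every library. At Cic the fold enrichment was 14.5 in replicate 1 and 6.78 in replicate 2, at Usp22 it was 19.1 and 6.31, and at Lars2 it was 23.5 and 19.4. The Lars2 peak had its summit inside the gene, 642 and 687 bp from the upper end. In replicate 2 its −log10 q was 102.6, against 12.5 at Cic, the next highest of the 10. With no control library here, signal that arises at the Lars2 site with any antibody was not separated from binding. Jun had a peak in replicate 1 with a fold of 15.4 and none in replicate 2.

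The second question was whether ATF2 phosphorylated at the 2 pairs of residues occupied different regions. Of the 7034 T69/71 regions, 4167 (59.2%, 58.1 to 60.4) had a peak in replicate 1 of S490/498, against a mean of 17.6 after shuffling. The share rose with the strength of the T69/71 region, from 19.9% in the weakest of 10 equal groups by fold enrichment to 96.0% in the strongest. Replicate 1 of S490/498 had a lower background coverage (0.0874) than the T69/71 libraries (0.117 and 0.105), and fewer peaks. A weak region without a peak there may thus have been missed, and depth was not separated from a difference in binding. Conversely, 75.6% (74.5 to 76.6) of the peaks in replicate 1 of S490/498 had a partner in either T69/71 library. None of its 579 peaks with −log10 q of at least 20 was absent from both T69/71 libraries, which allows a share of up to 0.635% by the exact interval. In replicate 1 of T69/71, 6 of 1308 such peaks were absent from the other 2 of these 3 libraries, and in replicate 2, 89 of 1309 (6.80%, 5.50 to 8.30). When only regions found in both libraries of each antibody were compared, 159 T69/71 regions overlapped S490/498 regions, a number set by the 435 peaks of replicate 2.

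**Figure D2:**
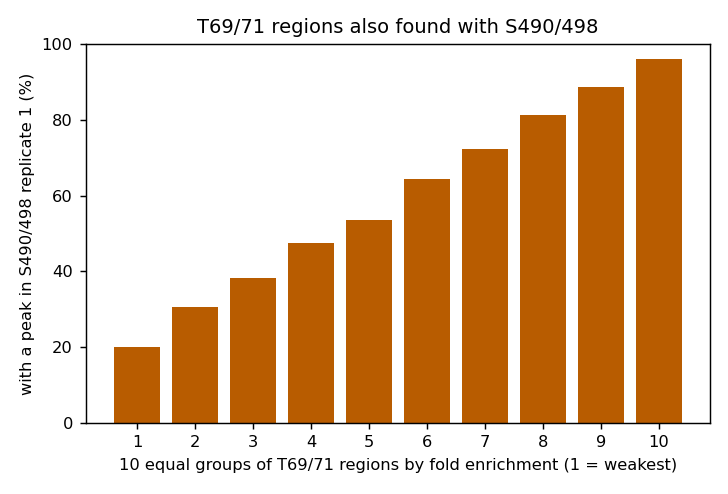
Regions shared by both T69/71 libraries were split into 10 equal groups by mean fold enrichment (x axis, 1 is the weakest), and the y axis gives the percentage that also had a peak in replicate 1 of S490/498. The percentage climbed from 19.9% to 96.0%.

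Replicate 1 of T69/71 resembled replicate 1 of S490/498 more than its own replicate 2 among strong peaks. Of the 435 strongest peaks in each library, replicate 1 of T69/71 shared 79.5% (75.4 to 83.2) with replicate 1 of S490/498 and 54.3% (49.4 to 59.0) with replicate 2 of T69/71. Among 7132 peaks per library these shares were 58.9% and 58.9%. At that size, replicate 2 of T69/71 shared 51.1% (49.9 to 52.2) with replicate 1 of S490/498, less than with its own replicate 1. Replicate 2 of S490/498 shared 16.3% to 20.0% of its 435 peaks with the strongest 435 of any other library. Across 4174 regions found in the 3 larger libraries, log2 fold enrichment correlated with Pearson r = 0.78 (Spearman rho = 0.73) between both replicates 1. It correlated with r = 0.60 (rho = 0.54) between the T69/71 replicates and r = 0.61 (rho = 0.53) between replicate 2 of T69/71 and replicate 1 of S490/498. These correlations are across regions, which are not independent replicates. With 3 ways to split 4 libraries into pairs, an exact permutation test of the antibody effect could not pass 0.05.

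**Figure D3:**
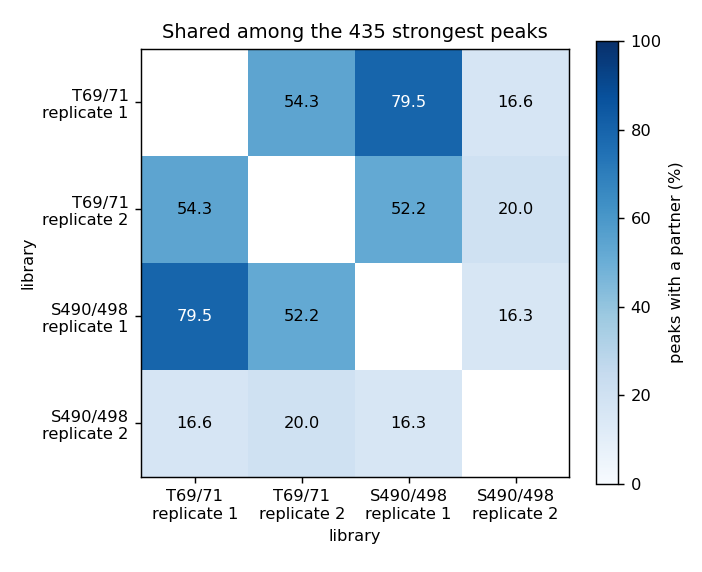
Each cell gives the percentage of the 435 strongest peaks of a library that overlapped one of the 435 strongest peaks of another library by at least 1 bp. The highest value, 79.5%, joins the libraries numbered 1 of the different antibodies, and values for replicate 2 of S490/498 lie between 16.3% and 20.0%.

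Peaks were concentrated at gene ends. Within 1 kb of a protein-coding gene end lay 42.1% (41.2 to 43.0) and 37.0% (36.2 to 37.8) of the peaks in the T69/71 libraries, 46.3% (45.1 to 47.4) in replicate 1 of S490/498 and 10.8% (8.05 to 14.1) in replicate 2. Shuffled peaks gave 3.17% to 3.23%. The means of the antibodies differed by 11.0 percentage points, higher for T69/71, which was less than the spread between the S490/498 libraries (exact permutation p = 1, where the smallest p that this design allows is 0.333). Against replicate 1 of S490/498 alone, without replicate 2, the difference turned to -6.71 points. Outside gene ends, 31.2%, 34.5%, 28.5% and 34.3% of peaks lay inside genes. In the 3 larger libraries, peaks at gene ends were stronger than the rest, with median −log10 q of 7.50 against 4.63, 8.23 against 5.63 and 6.73 against 4.47. In replicate 2 of S490/498 the order was the opposite, with 5.46 against 6.30. Of 21887 protein-coding genes, 4618 (21.1%) had a peak at an end in both T69/71 libraries and 3917 (17.9%) in replicate 1 of S490/498. Both sets held 3119 genes, where independent lists would share 826. In replicate 1 of T69/71, 230 of 6019 genes had a summit within 1 kb of both ends, which 1 summit can meet in a short gene.

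The third question was which gene groups carried these peaks. In both T69/71 libraries, 11 of 21 lists had more members with a peak than the other genes, by Fisher's exact test with Benjamini-Hochberg adjustment. The highest share was in the unfolded protein and integrated stress response, with 14 of 18 genes (77.8%, adjusted exact p = 6.1e-06). Its members included Hspa5, the chaperone BiP, with fold enrichments of 15.8 and 13.2 in replicates 1 and 2, and Calr, a calcium-binding chaperone, with 10.6 and 13.6. Hsp90b1 and Ppp1r15a, which encodes a phosphatase subunit that ends the response, were also marked. Among immediate early genes, 13 of 19 had a peak (adjusted exact p = 7.19e-05), such as Klf6 with folds of 20.9 and 21.8, Btg2, Btg1 and Nr4a3. AP-1, ATF and CREB factors had 17 of 29 (adjusted exact p = 7.19e-05), with peaks at Jun, Fosb, Atf3 and Atf7. At Atf3, a stress-induced family member, the folds were 14.1 and 8.34. The stress MAPK pathway had 17 of 29 (adjusted exact p = 7.19e-05), including Mapk8, the kinase JNK1, and the phosphatase genes Dusp1, Dusp8 and Dusp10.

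Genes of DNA replication and its checkpoints were also marked with T69/71. The replication stress and checkpoint list had 16 of 26 members with a peak (adjusted exact p = 7.19e-05), among them Atm, Wee1, Rpa2 and Zranb3. DNA replication had 17 of 32 (adjusted exact p = 3.48e-04), led by Gins2, a subunit of the replicative helicase, with folds of 15.5 and 18.2, and Pcna, the sliding clamp, with 12.3 and 13.6; Pold1 and Mcm7 were among the rest. Other DNA repair had 16 of 34 (adjusted exact p = 0.0037), with Mdc1 at 15.6 and 15.3, Mre11a and Parp2. Replication-dependent histones had 40 of 67 (adjusted exact p = 2.97e-10), although clustered neighbours such as H3c1 and H4c1, or H2ac6 and H2bc4, share a peak. The list of DEK and histone chaperones also holds Cbx genes. It had 12 of 20 members with a peak (adjusted exact p = 8.11e-04), including Cbx3, Asf1b, Ncl and Anp32b but not Dek. Housekeeping lists were also raised. Cytosolic ribosomal proteins had 28 of 45 (Rpl27, Rps16, Rpl4 and Rpl15 among them, adjusted exact p = 5.59e-08) and oxidative phosphorylation 15 of 30 (Cycs, Ndufb5, Ndufa4 and Atp5b, adjusted exact p = 0.0018). Peaks at Atm, Zranb3, Pcna, Pold1, Mcm7, Mre11a, Cbx3, Rpl4, Rpl15, Ndufb5 and Ndufa4, like those at Hsp90b1, Ppp1r15a and Dusp10 above, lay within 1 kb of the end of another gene and cannot be assigned to either.

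Cell cycle genes had 9 of 25 with a peak in both T69/71 libraries (36.0%, adjusted exact p = 0.208) and did not pass the test. Cdk4 had folds of 13.5 and 12.5, and Ccna2, Ccne1 and E2f3 were also marked. The list passed in replicate 2 alone (adjusted exact p = 0.0197 over 21 lists) and not in replicate 1 alone (adjusted exact p = 0.0563). The peak at Ccna2 lay within 1 kb of an end of Bbs7.

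No blood lineage list passed the test for peaks in both T69/71 libraries, in either direction. HSC-enriched genes had 5 of 32 (15.6%, adjusted exact p = 1), among them Zfpm1, Lyl1, Hlf and Runx1. Runx1, a regulator of blood stem cell emergence, is named outside the rule, after its values were seen. In each T69/71 library alone, 10 of the 32 (31.2%) had a peak, against 27.5% and 27.9% of other genes (adjusted exact p = 0.727 and 0.767 over 21 lists). Erythroid markers had 2 of 18 (Tfrc among them), megakaryocyte markers 1 of 15 (Itga2b), T and NK markers 2 of 16 (Cd3d, and Lat with its neighbour Spns1) and myeloid markers 4 of 18 (Cebpa, Mpo, Spi1 and Ctsg). None of these passed the test (adjusted exact p between 0.485 and 1). B lymphoid and stromal or endothelial markers had 0 of 13 each, with an upper exact limit of 24.7% (adjusted exact p = 0.208). Over 21 lists, both were called lower than other genes in replicate 1 alone (adjusted exact p = 0.0386 each, but 0.0773 over 42 tests) and not in replicate 2 alone (adjusted exact p = 0.169 each). The B lymphoid gene Ebf1 and the endothelial gene Kdr each had a peak in replicate 2 of T69/71 and in no other library. Neural genes, the negative control, had 0 of 20 (adjusted exact p = 0.0442), and Syn1 had a peak in replicate 2 of T69/71 and replicate 1 of S490/498. That call was lost with −log10 q of at least 5 (adjusted exact p = 0.181).

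**Figure D4:**
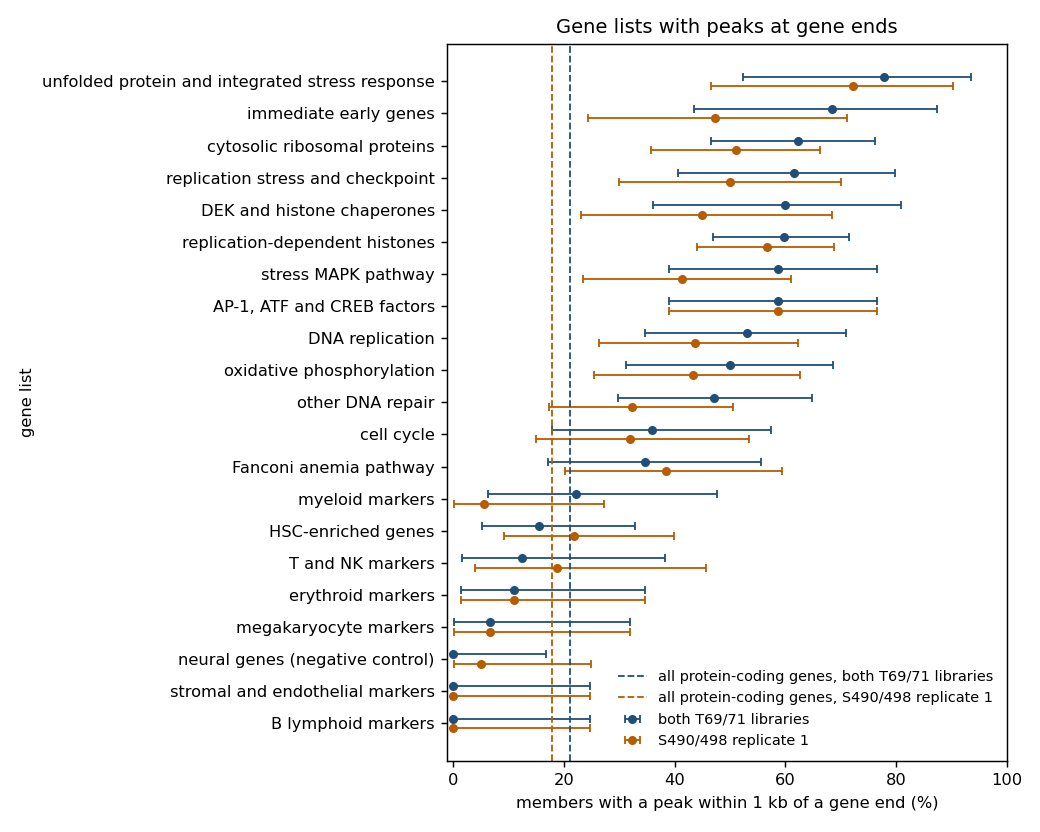
Points give the percentage of each list's members with a peak within 1 kb of a gene end in both T69/71 libraries (blue) and in replicate 1 of S490/498 (orange), with exact 95% binomial intervals; dashed lines mark all protein-coding genes at 21.1% and 17.9%. The stress-response, replication, histone and housekeeping lists lie to the right of the dashed lines, and the lineage and neural lists lie near or to the left of them.

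For S490/498, no list passed in the 39 genes marked in both libraries by Fisher's exact test, with 1 list at an unadjusted exact p under 0.05. With 0.18% of protein-coding genes marked, the test could hardly call a list. In the unfolded protein and integrated stress response, 1 marked gene of 18 gave an adjusted exact p of 0.102. These 39 genes included Atf7 (fold 6.93 and 6.35) and Calr (6.92 and 5.95). Replicate 2 alone had 1 list above other genes, AP-1, ATF and CREB factors, with 2 of 29 (adjusted exact p = 0.0403 over 21 lists). Replicate 1 alone, a single library without a replicate check, had 11 lists above other genes (adjusted over 21 lists). The unfolded protein and integrated stress response had 13 of 18 (adjusted exact p = 4.62e-06), AP-1, ATF and CREB factors 17 of 29 (adjusted exact p = 5.79e-06) and immediate early genes 9 of 19 (adjusted exact p = 0.0071). Replication stress and checkpoint had 13 of 26 (adjusted exact p = 8.0e-04), replication-dependent histones 38 of 67 (adjusted exact p = 2.35e-11) and ribosomal proteins 23 of 45 (adjusted exact p = 4.42e-06). In that library the fold was 14.7 at Atf3, 15.3 at Hspa5, 16.3 at Gins2 and 17.6 at Mdc1. Other DNA repair, the list that holds Mdc1, did not pass there, with 11 of 34 (adjusted exact p = 0.0709 over 21 lists).

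Fanconi anaemia genes were marked in part. In both T69/71 libraries 9 of 26 had a peak (34.6%, adjusted exact p = 0.223), which did not pass the test. Over 21 lists, it passed in replicate 2 alone (53.8%, adjusted exact p = 0.012) and not in replicate 1 alone (46.2%, adjusted exact p = 0.0599). In replicate 1 of S490/498, 10 of 26 had one (38.5%, adjusted exact p = 0.032 over 21 lists), and the difference between the antibodies was not tested. Brca1, a recombination factor, had folds of 9.44 and 10.3 in the T69/71 libraries and 10.1 in replicate 1 of S490/498. Its peak in replicate 1 of T69/71 spanned chromosome 11, 101551944 to 101552935, where the gene Nbr1 also ends, and the peak at Rad51c lay near Tex14. Fance, a core complex subunit, had 7.66, 11.9 and 8.57, Rad51c 10.5, 7.80 and 7.89, and the nuclease scaffold Slx4 8.95, 8.65 and 6.05.

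Dek had no peak within 1 kb of its ends in any of the 4 libraries. Dek lies on chromosome 13, 47084767 to 47107530. One peak lay over the gene, in replicate 1 of T69/71, at 47106324 to 47106521, with its summit 1170 bp inside the upper end, a fold of 5.56 and −log10 q of 4.46. No peak lay over Dek in the other T69/71 library or in either S490/498 library, whose nearest summits were 41.5 kb, 41.4 kb and 1018 kb from the gene. Atf2 itself, on chromosome 2 at 73816509 to 73892677, had a peak at its upper end in replicate 2 of T69/71 (fold 7.43) and replicate 1 of S490/498 (fold 7.40).

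Of the 5 strongest T69/71 regions away from gene ends, 4 had a peak in all 4 libraries, and the one on chromosome 16 had none in replicate 2 of S490/498. The leading 5 for T69/71 lay on chromosome 12 at 120028658 to 120029024, 7.59 kb from Tmem196, on chromosome 2 at 98666240 to 98667315, 1035 kb from Lrrc4c, and on chromosomes 16, 8 and 14, nearest B230307C23Rik, Adgre5 and Fgf14. The leading 5 for S490/498 replaced the chromosome 16 region with one on chromosome 14 at 19416831 to 19419440, 116 kb from Gm2244. At the chromosome 12 region the fold was 47.0 and 57.9 in the T69/71 libraries and 46.0 and 30.1 in the S490/498 libraries. None of these regions lay inside a protein-coding gene. With no control library here, signal that arises at such regions with any antibody was not separated from binding.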

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

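The tests in this part were chosen after the results they concern were seen. Peaks outside chromosomes 1-19, X and Y took no part in the comparisons and numbered 25 and 28 in the T69/71 libraries, 16 in replicate 1 of S490/498 and 41 in replicate 2. They are given as signal in data outside the comparisons, with no control library and no expected number to set beside them.

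Replicate 2 of S490/498 had 435 peaks, 10.8% of them at gene ends. Too few reads would have given a low background, but the recovered background was 17.4 times that of the lowest other library. At 33 regions near gene ends with a peak in all 4 libraries, its fold, taken over its own background, lay below that of replicate 1 at all 33, with a median log2 difference of -1.07. This is consistent with low enrichment over a deep background, and whether the cells, the antibody step or duplicated reads caused it is open. The design gives both libraries as the same cells, so no biological explanation was tested.

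Among the 435 strongest peaks and in fold correlation, replicate 1 of T69/71 resembled replicate 1 of S490/498 more than its own replicate 2. Among 7132 peaks per library it shared 58.9% with each. Signal present in every library whatever the antibody stays open: leaving out regions under a peak of replicate 2 of S490/498 removed only 159 of 4174, so the remaining r of 0.76 with S490/498 and 0.57 with T69/71, a difference of 0.19, decides nothing. Molecules shared between the libraries, as from swapped indices, could give more identical peak starts. The shares were 5.65% with replicate 1 of S490/498 and 5.23% with replicate 2 of T69/71, a difference of 0.42 points (95% interval -0.40 to 1.25). The interval takes pairs of peaks as independent, although both shares use the peaks of replicate 1 of T69/71. Shared molecules stay open, because a peak start also depends on each library's background and no mixture of libraries was simulated. A common batch of the libraries numbered 1 cannot be told apart from common signal or binding: replicate 2 of T69/71 shared 20.0% of its 435 strongest peaks with replicate 2 of S490/498, and the interval of 16.3 to 24.1 holds the 16.6% of replicate 1. The peak names begin with ATF2-1 and P-ATF-1 in replicates 1 and 2 of T69/71 and with ATF2-2 in both S490/498 lists. Their number thus follows the antibody in all 4 lists, whereas the number in the titles is the replicate. Their wording sets replicate 2 of T69/71 apart from the other 3, and whether the names bear on this resemblance was not tested. Binding of both forms at the same sites stays open.

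Stress-response genes were often marked, and this may reflect active promoters in general. Of 95 genes in the AP-1, MAPK, immediate early and unfolded protein lists, 64.2% (53.7 to 73.8) had a peak in both T69/71 libraries, against 57.3% (45.4 to 68.7) of 75 ribosomal and oxidative phosphorylation genes (Fisher's exact p = 0.429). The marked stress-response and housekeeping genes, however, differed in strength. The stress-response genes had a median −log10 q of 16.8 against 9.69 (permutation p = 1.2e-04) and a median fold of 9.31 against 7.86 (permutation p = 0.0158). Other active promoters were not compared, and genes are not replicates. In replicate 1 of S490/498 the median −log10 q was 9.91 against 6.36 (permutation p = 0.0018). Sites for ATF2 in these promoters were not counted, so stronger binding and wider open chromatin both remain possible.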

How the results depend on the processing

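The 7034 regions of T69/71 stayed within 1.5 times under the other overlap rules, the stricter threshold and the filters (4763 to 6871), and fell to 236 with the 435 strongest peaks, by construction. The 174 regions of S490/498 ranged from 119 to 142 and fell to 70 with the 435 strongest. The 159 regions common to both antibodies became 98 with summits within 200 bp, 103 with −log10 q of at least 5, 58 with the 435 strongest peaks and 100 on autosomes without the widest regions. Leaving out 1 library gave 162 to 4167 of them, the latter without replicate 2 of S490/498, so that library sets the number. Chosen after seeing the data, leaving out regions under a peak of replicate 2 of S490/498 gave 6849 T69/71 regions, of which 58.5% had a peak in replicate 1 of S490/498, and the stricter threshold gave 58.5%. The difference in the share at gene ends ranged over -6.71 to 28.7 points when 1 library was left out, and reversed to -6.71 without replicate 2 of S490/498. It rose to 19.9 with the 435 strongest peaks and, chosen after seeing the data, to 20.5 with at most 7132 (exact permutation p = 0.667 each). With the replicate block, the difference was 11.0 points (exact sign-flip p = 1, smallest possible 0.5), from -4.14 within number 1 and 26.2 within number 2. The numbers are not stated to pair libraries, and the differences between numbers 1 and 2 in the presence of peaks correlated with r = 0.10 between the antibodies. The 11 lists of T69/71 remained within 3 kb, with a peak in either library, with −log10 q of at least 5 and without each T69/71 library, the alternatives run on lists. Fanconi anaemia genes (adjusted exact p = 0.0032 and 0.024) and cell cycle genes (adjusted exact p = 0.0055 and 0.0393) joined them with a peak in either library and without replicate 1, adjusted over 42 tests, giving 11 to 13 lists. The neural list lost its call with −log10 q of at least 5 and, over 42 tests, without replicate 1 (adjusted exact p = 0.0667), but not over 21 lists (0.0334). HSC-enriched genes went from 15.6% to 31.2% without either library and 46.9% with a peak in either, without a call. For S490/498, 0 lists became 1 within 3 kb (AP-1, ATF and CREB factors), 11 with a peak in either library, and 1 to 11 when 1 library was left out. Dek went from 0 to 1 library within 3 kb of its ends and 1 with any peak over the gene, in both cases replicate 1 of T69/71. Without the pseudocount in the fold, whole pileups were found for 0.241% and 0.312% of peaks with T69/71 and 0.238% and 0.219% with S490/498. Motif counts, the CpG-rich background and left-out libraries within a pair of 2 could not give values. A median pileup of 8 or 9 fragments limits what weak peaks can show, and the cause of the changes not set by construction was not tested.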

Other observations

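The comparisons in this part were chosen after the data were seen. Genes whose end lay within 1 kb of another protein-coding gene's end were marked more often. Of 5426 such genes, 38.9% had a peak in both T69/71 libraries, against 15.2% of the other 16461, and in replicate 1 of S490/498 the shares were 34.4% and 12.5%. Part of this follows from counting 1 peak for both neighbours. Among genes over 2 kb from any protein-coding gene end, 24 of 341 transfer RNA genes (7.04%, 4.56 to 10.3) had a T69/71 peak in both libraries and 19 (5.57%) in replicate 1 of S490/498. Long noncoding RNA genes stood at 2.35% of 10007, small nuclear RNA genes at 2.46% of 935, small nucleolar RNA genes at 0.342% of 1171 and pseudogenes at 0.160% of 9389. In replicate 2 of S490/498, 0 of 341 transfer RNA genes had a peak, with an upper exact limit of 1.08%. In these counts too, genes that lie close together can share 1 peak, and the intervals take genes as independent.

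Of the 1000 strongest peaks in replicate 2 of T69/71, 66 were absent from replicate 1 and from replicate 1 of S490/498. Only 8 of the 66 (12.1%) lay at gene ends, against 58.9% of the others, and their median width was 293 bp against 423 bp. The strongest lay on chromosome 9 at 110281245 to 110281408, 18.7 kb from Cspg5, with a fold of 38.8. A peak in replicate 2 of S490/498 was present at 3 of the 66, against 110 (11.8%) of the others. Among the 20 peaks with the highest −log10 q, fold enrichment ranged from 16.4 to 47.8 and 8.25 to 57.9 in the T69/71 libraries, and from 16.1 to 46.8 and 4.85 to 30.1 in the S490/498 libraries. The highest −log10 q values were 902, 1074, 694 and 11207 in the same order, the last at the chromosome 2 region near 98666240, where the fold was 16.1.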
